A study of Homo sapiens with 12 samples.

How the data were processed

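Gene expression was measured in HT29 cells, an established human colon adenocarcinoma line, with Affymetrix human gene arrays, which hold several short probes spread along each transcript. The 12 arrays form 4 groups of 3. They are a control group, taken as 0 h, and groups after 8, 24 and 48 h with 70 nM methotrexate. Group, replicate number and the times of the treated groups were taken from the sample titles, which call the replicates biological. The titles give neither the dose nor a time for the control. No array was left out.

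The deposited values are on a log2 scale, with 1 value per probe set and array. The submitters' processing notes name RMA, which corrects background, normalizes between arrays and summarizes the probes of a set, and the genome build hg19, both without a version. In the deposited values the median of the 3 control arrays was exactly 0 in all 28869 probe sets, so each value is a log2 ratio to the control median. That centring step is not given in the sources used here, and the base of the logarithm was taken from RMA. Absolute levels are lost by the centring, so the signal over background of a gene is unknown. A shift by a constant per probe set leaves the differences between groups as they were.

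Probe sets were named with the platform annotation given for this series. Of the 28869 probe sets, 19310 had 1 gene symbol, 1752 had several and 7807 had no gene named here. Probe sets with several genes or none were kept out of the tests of genes and were tested apart. The gene ID led to an updated symbol in 0 cases, and the gene ID of 31 single-gene probe sets was not in the gene table used. Before the data were examined, the plan was to take the brightest probe set of each gene. With no level left this could not be done, and the mean of a gene's single-gene probe sets, listed beforehand as the other choice, was used instead. It applied to 685 of the 18377 genes, and the other genes had 1 probe set each.

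Differences between groups were fitted with limma 3.58.1 in R 4.3.3. All 12 arrays entered a single linear model with a mean per group (lmFit, contrasts.fit, eBayes), which gave 8 residual and 4.71 prior degrees of freedom. Each of the 3 treated groups was compared with control, 24 h with 8 h, and 48 h with 24 h, 5 comparisons in all. Differences among the 4 groups were tested with limma's moderated F statistic. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 18377 genes of a comparison. The error given with a fold change is limma's moderated standard error. Principal components were computed from the gene values of all arrays. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

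The 28 gene lists, the tests and most alternatives were fixed before the data were examined. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01 between genes. The p-values were adjusted over the 84 list tests against control and separately over the 56 tests of the consecutive comparisons. Camera with a correlation estimated from the residuals and limma's fry, which tests whether the genes of a list move on balance in a single direction, were alternatives. The calls of a list's members were also adjusted over the list alone. A list's median is the median of its members' log2 fold changes, and the error of some medians was taken from 1000 bootstrap draws of the members.

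The rule for named genes was also fixed beforehand. For each comparison with control it takes the 6 largest rises and 6 largest falls among called genes whose 3 treated values all lie on one side of the 3 control values. From each list it takes up to 4 called members with the largest change, or the 2 members with the smallest p where fewer than 2 were called. For each consecutive comparison it takes the 3 largest rises and falls. Symbols such as pseudogenes and small RNAs could be skipped among these, with the next in order taken. This left out 2 rises at 8 h against control, NMRAL2P and RNU5D-1, and 1 fall at 24 h against 8 h, SNORD14E. A further 13 genes of folate use, the cell cycle and differentiation were to be named whatever their p, and 10 of them were analysed here. Examples from some lists are left out for length.

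The 3 comparisons with control share the same 3 control arrays. The overlap of their calls was set beside that of independent lists and beside 100 simulations of unchanged groups. In these all 12 arrays were drawn anew from the residuals, and the 3 comparisons shared the simulated controls. Whether chance groupings of the arrays call as many genes was tested on all 10 splits of the arrays of each pair of groups and on 100 splits of the 12 arrays.

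Alternatives fixed beforehand were the replicate number as a block, array weights, centring each array on its median, a robust prior, fits of only the 2 groups compared, every probe set on its own, stricter thresholds (adjusted p under 0.01, at least a 1.5-fold change, and limma's treat against a 1.2-fold change), and leaving out each array in turn. The main axis of the residuals as a covariate and only genes with a single probe set were added after seeing the data. Some choices listed beforehand could not be run on values centred on the controls and are named with the other limits.

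The fit was tested on simulated data with the real spread of each gene, pooled over the groups and drawn independently for each gene and array. In these data 200 of 18377 genes were changed. For 8, 24 and 48 h against control, 49.3%, 55.2% and 59.7% of the genes changed by 0.3 on the log2 scale were recovered, 97.0%, 91.0% and 94.0% of those changed by 0.6, and 100% of those changed by 1. For 24 h against 8 h the shares were 59.7%, 92.5% and 98.5%, and for 48 h against 24 h they were 47.8%, 89.6% and 100%. Of the genes called in these simulations, 5.75%, 6.29% and 8.65% were unchanged against control at 8, 24 and 48 h, 4.02% for 24 h against 8 h and 4.24% for 48 h against 24 h. In simulated data with no change, 0 genes were called in each comparison. In each comparison camera called a simulated list of 40 genes shifted by 0.2 and 0 of 20 unchanged lists. The simulated genes were independent, while 50.5% of the real residual variance lay on the main axis. These simulations therefore do not give the share of false calls, of genes or of lists, under such a correlation. They also gave all groups the same spread, while the real root mean square SD was 0.120 at 48 h and 0.086 to 0.089 in the other groups. Far fewer genes were changed than the 10.1% to 25.3% called in the real comparisons. The shares recovered may therefore differ in the real data. The precision is limited by the number of arrays.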

Results

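HT29 cells, a human colon adenocarcinoma line, were profiled after 8, 24 and 48 h with 70 nM methotrexate. A control group, taken as 0 h, was profiled too. Methotrexate is an antifolate that lowers the supply of reduced folates needed to make thymidylate and purines. Each of the 4 groups held 3 arrays, and 18377 genes were tested. The deposited values were log2 ratios to the control median, so differences between groups were measured and absolute levels were not. The median SD of a gene between replicates was 0.08 on the log2 scale, and the median SE of a difference between groups was 0.07. By group the median SD was 0.064 for control, 0.065 at 8 h, 0.066 at 24 h and 0.087 at 48 h. The fit pools the spread over the groups, so a gene has the same SE at each time. Those SEs may be too small at 48 h and too large at 8 and 24 h. No untreated array at 8, 24 or 48 h was used here. With the control taken as 0 h, treatment and time in culture therefore changed together in every comparison with control.

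Expression of 7122 genes (38.8%) differed among the 4 groups by limma's moderated F test. The first principal component, with 40% of the variance, ran from the 8 h arrays (scores -17.9 to -16.6) through control and 24 h to the 48 h arrays (17.2 to 21.9). The second, with 29.1%, set the control arrays (16.8 to 20.3) apart from the treated arrays. Replicate 3 of the 48 h group stood apart from its group. It differed from replicate 1 by a root mean square of 0.21 over genes, against 0.09 to 0.18 for the other replicate pairs of the 4 groups. It also had the lowest array weight, 0.199, and the highest score, 0.608, on the main axis of the residuals. Without this array, 4439 genes were called at 48 h against control, compared with 4649 with it. With array weights the 48 h values rest mostly on replicate 2, which had a weight of 6.52 against 0.797 for replicate 1.

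**Figure D1:**
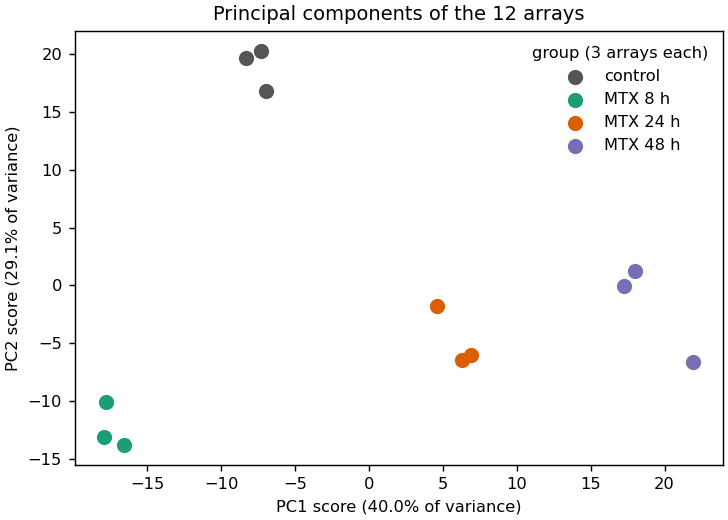
Scores of the 12 arrays on the first principal component (horizontal, 40% of variance) and the second (vertical, 29.1%); each point is an array and colours mark the 4 groups of 3. The 8 h arrays lie at -17.9 to -16.6 on the first component and the 48 h arrays at 17.2 to 21.9.

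After 8 h, the comparison with control showed which genes differed early in exposure, and interferon-stimulated genes had the largest shift of the 28 lists. Of 38 measured, 36 fell and 0 rose, and 38 fell when adjusted over the list alone. The list median was -1.45 (bootstrap SE 0.09), and the median was -1.49 to -1.35 on the 3 treated arrays. IFI44L was 10.1-fold lower (log2 fold change -3.34, SE 0.12, n = 3 per group), MX2, an antiviral GTPase, 9.27-fold lower (-3.21, SE 0.12) and IFIT1, which binds viral RNA, 5.58-fold lower (-2.48, SE 0.08). XAF1 (-2.57, SE 0.13), RSAD2 (-2.42, SE 0.08) and MX1 (-2.35, SE 0.10) completed the 6 largest falls among all genes. For the list, camera gave an adjusted p = 1.61e-49, and adjusted p = 0.00993 with an estimated correlation.

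Genes of the integrated stress response, which controls amino acid supply under stress, also fell at 8 h: 28 of 34 fell and 1 rose, or 29 and 2 adjusted over the list alone. DDIT4, an inhibitor of mTORC1, fell by 2.26 (SE 0.08), CHAC1, a glutathione-degrading enzyme, by 1.98 (SE 0.06) and the transcription factor DDIT3 by 1.44 (SE 0.07). The list median was -0.57 (adjusted p = 3.35e-26, and adjusted p = 0.00993 with an estimated correlation). Of 34 immediate early genes, which follow growth factor signalling, 22 fell and 1 rose (24 and 1 adjusted over the list alone), with a median of -0.28. EGR1 fell by 1.29 (SE 0.07) and SPRY4, a feedback inhibitor of that signalling, by 1.03 (SE 0.06). The list test gave adjusted p = 6.12e-12, and adjusted p = 0.0212 with an estimated correlation. Of 45 replication-dependent histone genes, 28 fell and 0 rose (32 and 0 adjusted over the list alone), with a median of -0.32 (adjusted p = 3.57e-14, and adjusted p = 0.0261 with an estimated correlation). H2BC3 fell by 1.64 (SE 0.10). Histone genes of these clusters are near-identical copies, so the values of single members are uncertain.

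Genes of DNA replication and the G1/S transition rose at 8 h: 49 of 50 rose and 0 fell, with the same 49 and 0 adjusted over the list alone. ORC1, of the origin recognition complex, rose 2.21-fold (1.14, SE 0.05), the replication fork protein CLSPN 2.19-fold (1.13, SE 0.11) and MCM10 2.09-fold (1.06, SE 0.08). Cyclin E2, CCNE2, rose by 0.97 (SE 0.06). The list median was 0.55, and 0.53 to 0.59 on the 3 arrays (adjusted p = 6.76e-35, and adjusted p = 0.0166 with an estimated correlation). Among purine synthesis genes 15 of 17 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 0.35. PFAS, of the de novo pathway, rose by 0.60 (SE 0.07) and the salvage enzyme HPRT1 by 0.58 (SE 0.06). That list gave adjusted p = 2.22e-07, and adjusted p = 0.0223 with an estimated correlation. Of 20 pyrimidine and deoxynucleotide genes 12 rose and 3 fell (12 and 4 adjusted over the list alone), with CTPS1, the CTP synthase, up by 0.92 (SE 0.05) and SAMHD1, which degrades deoxynucleotides, down (-0.93, SE 0.09). The median was 0.27 (adjusted p = 0.000916, and adjusted p = 0.312 with an estimated correlation).

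Of 37 ribosome biogenesis genes 29 rose at 8 h and 0 fell (32 and 1 adjusted over the list alone), among them LYAR (0.93, SE 0.08) and MRTO4 (0.75, SE 0.06). The list median was 0.38 (adjusted p = 4.03e-15, and adjusted p = 0.0508 with an estimated correlation). Of 34 DNA damage repair genes 23 rose and 0 fell (24 and 0 adjusted over the list alone), among them the ubiquitin ligase RAD18 (0.93, SE 0.08) and the exonuclease EXO1 (0.88, SE 0.08). That list's median was 0.36 (adjusted p = 4.05e-12, and adjusted p = 0.279 with an estimated correlation). Of 22 NRF2 targets, antioxidant and NADPH genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone). AKR1B10, an aldo-keto reductase, rose 2.88-fold (1.53, SE 0.09), AKR1C2 2.38-fold (1.25, SE 0.09) and GCLM, of glutathione synthesis, 1.93-fold (0.95, SE 0.11). The median was 0.30 (adjusted p = 8.70e-10, and adjusted p = 0.00993 with an estimated correlation). The largest rises among all genes also included TNC, a matrix glycoprotein (1.62, SE 0.09), the calcium sensor VSNL1 (1.49, SE 0.12), the caveolar protein CAV1 (1.24, SE 0.10) and ALDH3A1 (1.22, SE 0.08). A pseudogene and a small RNA, NMRAL2P and RNU5D-1, were skipped among them under the rule for named genes.

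Of 24 folate genes 9 rose and 5 fell at 8 h (10 and 5 adjusted over the list alone). The list was not past the threshold against other genes (adjusted p = 0.446), while fry, which makes no such comparison, gave adjusted p = 0.0198. TYMS, which makes thymidylate, rose 1.63-fold (0.70, SE 0.05). The reduced folate carrier SLC19A1 rose by 0.33 (SE 0.06) and FPGS, which adds glutamates to folates, by 0.40 (SE 0.07). The folate receptor FOLR1 fell by 0.84 (SE 0.06) and the mitochondrial enzyme MTHFD2 by 0.53 (SE 0.06). GGH, which removes glutamates, differed by 0.19 (SE 0.07, adjusted p = 0.0803), and passed the threshold without 24 h replicate 2 (0.0406) or 48 h replicate 3 (0.0466), with array weights (0.0365), in a fit of only these 2 groups (0.0261) and with the main residual axis as a covariate (0.00467). CDKN1A, a cyclin-dependent kinase inhibitor, fell by 0.45 (SE 0.06), and the mucin MUC2 rose by 0.21 (SE 0.05). MYC differed by 0.07 (SE 0.06, adjusted p = 0.487). MKI67, a proliferation marker, was higher by 0.36 (SE 0.11, adjusted p = 0.0331), and this was lost without any 1 of the 6 arrays compared (0.0501 to 0.122) and with each array centred (0.0556).

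Of 11 genes studied earlier in methotrexate-resistant lines, 5 rose at 8 h and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.08 and adjusted p = 0.0408. The adjusted p = 0.168 with an estimated correlation, and the call was lost without control replicate 3 (0.0570) or 8 h replicate 2 (0.0554), with array weights (0.0538) and with the main residual axis as a covariate (0.0557). Of 30 goblet cell markers 2 rose and 8 fell (2 and 8 adjusted over the list alone), among them CREB3L1 (-1.34, SE 0.10) and AGR2 (-0.91, SE 0.06), with a median of -0.02 and adjusted p = 0.0473. The adjusted p = 0.470 with an estimated correlation, and this call was lost with each array centred (0.0507), with array weights (0.0891), in a fit of only these 2 groups (0.0852), with the main residual axis as a covariate (0.0837) and over genes with a single probe set (0.0503). It was also lost without control replicate 2 or 3, 8 h replicate 1 or any array of the 24 h or 48 h groups (0.0502 to 0.101). For p53 targets, 6 of 32 rose and 12 fell (adjusted p = 0.0597), which passed the threshold without control replicate 3 (0.0341) or 8 h replicate 1 (0.0468). For apoptosis genes, 5 of 30 rose and 12 fell (adjusted p = 0.0624), which passed without control replicate 3 (0.0391).

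The other 13 lists were not past the threshold at 8 h, with 9 mitotic genes of 42 higher and 4 lower (adjusted p = 0.774). Methotrexate carriers had 5 of 16 higher and 2 lower (0.241), NF-kB and cytokine genes 3 of 29 higher and 9 lower (0.205), and hypoxia and glycolysis genes 8 of 30 higher and 8 lower (0.486). Of the unfolded protein response and heat shock genes 7 of 22 were higher and 5 lower (0.612), and of cholesterol synthesis genes 4 of 20 were higher and 4 lower (0.808). Enterocyte markers had 2 of 33 higher and 5 lower (0.932), stem cell and Wnt targets 5 of 28 higher and 4 lower (0.740), and enteroendocrine markers 1 of 18 each way (0.543). The median, mean and test differed in sign for the unfolded protein response, enterocyte and stem cell lists. Ribosomal proteins had 1 of 31 higher and 3 lower (0.412), and epithelial identity genes 1 of 12 higher and 3 lower (0.290). Of the markers of other cell types, FN1 alone of 22 fibroblast markers (0.43, SE 0.10; list 0.648) and CD68 alone of 18 leukocyte and endothelial markers (0.35, SE 0.06; list 0.817) were called. In the 16 lists not past the threshold, counts adjusted over the list alone differed from these by at most 1 higher and 1 lower member.

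In all, 2225 genes rose and 2214 fell at 8 h, 24.2% of those tested, and 21 rose and 107 fell at least 2-fold. Of the called genes 50.1% were higher, against 45.2% with each array centred, 42.8% without 8 h replicate 1 and 36.6% with at least a 1.5-fold change. The 3 treated values of 37.9% of genes did not overlap the 3 control values, a share that is 10% by chance.

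**Figure D2:**
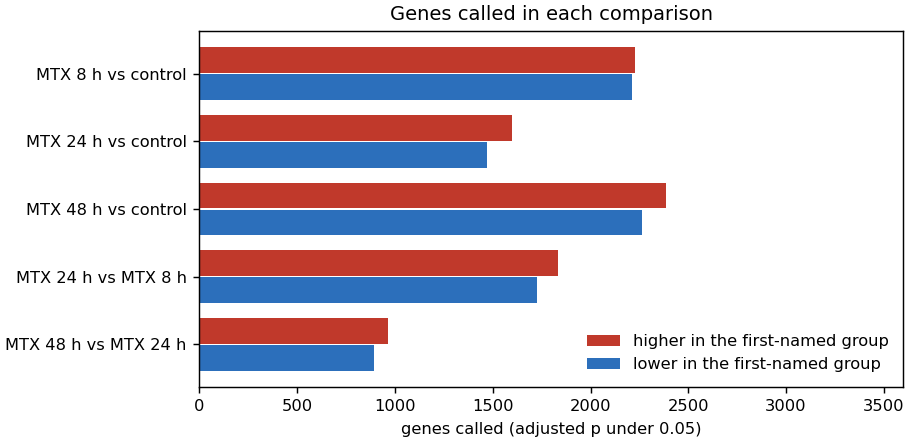
Number of genes called (horizontal) in each of the 5 comparisons, with bars for genes higher and lower in the first-named group (limma, adjusted p under 0.05, n = 3 arrays per group). At 48 h against control 2388 were higher and 2261 lower, and at 48 h against 24 h 966 were higher and 894 lower.

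After 24 h, replication-dependent histone genes had the most significant shift. Of 45 measured, 43 were lower than control and 0 higher (44 and 0 adjusted over the list alone), with a median of -0.96 (bootstrap SE 0.06) and -1.05 to -0.92 on the 3 arrays. H2BC3 fell 4.54-fold (-2.18, SE 0.10, n = 3 per group), H3C12 4.29-fold (-2.10, SE 0.07) and H2AC4 3.57-fold (-1.83, SE 0.08). The list test gave adjusted p = 1.99e-58, and adjusted p = 0.00309 with an estimated correlation. Of 38 interferon-stimulated genes, 36 were again lower and 0 higher (37 and 0 adjusted over the list alone), with a median of -1.01 (adjusted p = 1.42e-50, and adjusted p = 0.00993 with an estimated correlation). IFI44L fell 8.11-fold (-3.02, SE 0.12), IFIT1 4.06-fold (-2.02, SE 0.08) and OAS2, a sensor of double-stranded RNA, 4.05-fold (-2.02, SE 0.09). Integrated stress response genes were lower in 24 of 34 cases and higher in 0 (26 and 1 adjusted over the list alone), with a median of -0.37 (adjusted p = 6.92e-20, and adjusted p = 0.0192 with an estimated correlation). DDIT4 fell by 1.72 (SE 0.08) and CTH, of cysteine synthesis, by 1.03 (SE 0.07).

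Of 50 replication and G1/S genes 45 rose at 24 h and 0 fell (46 and 0 adjusted over the list alone), with a median of 0.48 (adjusted p = 1.48e-30, and adjusted p = 0.0205 with an estimated correlation). CDT1, which licenses replication origins, rose 2.24-fold (1.16, SE 0.11) and ORC1 1.96-fold (0.97, SE 0.05). Of 42 mitotic genes, 18 fell and 4 rose (21 and 6 adjusted over the list alone), with a median of -0.12 (adjusted p = 0.000194, and adjusted p = 0.452 with an estimated correlation). KIF20A, a mitotic kinesin, fell by 1.16 (SE 0.08) and the mitotic kinase AURKA by 0.56 (SE 0.06). DNA damage repair genes rose in 19 of 34 cases and fell in 0 (22 and 0 adjusted over the list alone), with a median of 0.27 (adjusted p = 5.05e-10, and adjusted p = 0.349 with an estimated correlation). NRF2 targets rose in 11 of 22 cases and fell in 1 (12 and 1 adjusted over the list alone), with a median of 0.16 (adjusted p = 0.000101, and adjusted p = 0.0481 with an estimated correlation). Immediate early genes fell in 12 of 34 cases and rose in 5 (14 and 6 adjusted over the list alone), with a median of -0.12 (adjusted p = 0.000192, and adjusted p = 0.164 with an estimated correlation).

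Of the genes studied in resistant lines, 6 of 11 rose at 24 h and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.38 (adjusted p = 0.00781, and adjusted p = 0.0896 with an estimated correlation). CAV1 rose 3.08-fold (1.62, SE 0.10) and the neuronal enolase ENO2 1.45-fold (0.53, SE 0.05). Of 31 ribosomal proteins 5 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.04 (adjusted p = 0.00847, and adjusted p = 0.164 with an estimated correlation). Many ribosomal protein genes have processed pseudogenes that the probes can share. Of 29 NF-kB and cytokine genes 9 rose and 2 fell (10 and 2 adjusted over the list alone), among them IL18 (1.46, SE 0.11) and CXCL8 (0.71, SE 0.11). Their median was 0.09 and adjusted p = 0.0410, with adjusted p = 0.213 with an estimated correlation. That call was lost without control replicate 1 (0.0978) or 24 h replicate 3 (0.0536), with array weights (0.0576) and with the main residual axis as a covariate (0.0557). Other large rises were SH3TC2 (1.60, SE 0.08), LAPTM5, a lysosomal membrane protein (1.53, SE 0.13), VSNL1, 2.83-fold (SE 0.12 on the log2 scale), and the membrane-anchored semaphorin SEMA7A (1.44, SE 0.09).

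At 24 h TYMS was 1.60-fold higher than control (0.68, SE 0.05), and MYC fell by 0.42 (SE 0.06). SLC19A1 (-0.11, SE 0.06, adjusted p = 0.289), FPGS (0.10, SE 0.07, 0.401), GGH (0.17, SE 0.07, 0.149), MTHFD2 (-0.01, SE 0.06, 0.943), CDKN1A (0.06, SE 0.06, 0.661) and MKI67 (0.00, SE 0.11, 0.994) were not called, GGH passing the threshold with the main residual axis as a covariate (0.0131). CCNE2 was higher by 0.25 (SE 0.06, adjusted p = 0.0120), which was lost without control replicate 2 (0.0571). MUC2 was higher by 0.17 (SE 0.05, adjusted p = 0.0273), which was lost without any 24 h array or control replicate 1 or 2 (0.0580 to 0.116). Lists not past the threshold at 24 h were folate genes (3 of 24 higher, 4 lower; adjusted p = 0.575), purine synthesis (5 of 17 higher, 1 lower; 0.172), pyrimidine and deoxynucleotide synthesis (7 of 20 higher, 3 lower; 0.125), methotrexate carriers (1 each way; 0.559) and p53 targets (4 of 32 higher, 5 lower; 0.449). Ribosome biogenesis genes (3 of 37 higher, 6 lower; 0.0726) passed it without control replicate 3 (0.0156), with array weights (0.0205) or with the main residual axis as a covariate (0.0266).

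CEACAM6, an adhesion molecule of enterocytes, rose 2.23-fold at 24 h (1.16, SE 0.08), and CREB3L1 of the goblet list fell by 1.29 (SE 0.10), while neither list was past the threshold. Enterocyte markers had 4 of 33 higher and 2 lower (adjusted p = 0.392), goblet markers 2 of 30 higher and 5 lower (0.412), stem cell and Wnt targets 5 of 28 higher and 6 lower (0.434), and enteroendocrine markers 0 of 18 higher and 1 lower (0.715). Apoptosis genes (4 of 30 higher, 3 lower; 0.952), the unfolded protein response and heat shock (5 of 22 higher, 3 lower; 0.935), cholesterol synthesis (1 of 20 higher, 4 lower; 0.312) and hypoxia and glycolysis (6 of 30 higher, 5 lower; 0.612) also missed the threshold. So did epithelial identity (3 of 12 higher, 1 lower; 0.576), leukocyte and endothelial (1 of 18 higher, 0 lower; 0.486) and fibroblast markers (3 of 22 higher, 0 lower; 0.131), the last passing it with array weights (0.0412). FN1 was higher by 0.63 (SE 0.10) and CD68 by 0.85 (SE 0.06). The median, mean and test differed in sign for the folate, unfolded protein response, goblet and stem cell lists. In the 17 lists not past the threshold, counts adjusted over the list alone differed from these by at most 1 higher and 2 lower members.

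In all, 1597 genes rose and 1473 fell at 24 h, 16.7% of those tested, with 33 and 74 changed at least 2-fold. The groups did not overlap for 33.0% of genes, against 10% by chance. The count was 6079 with array weights and 5234 with the main residual axis as a covariate.

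**Figure D3:**
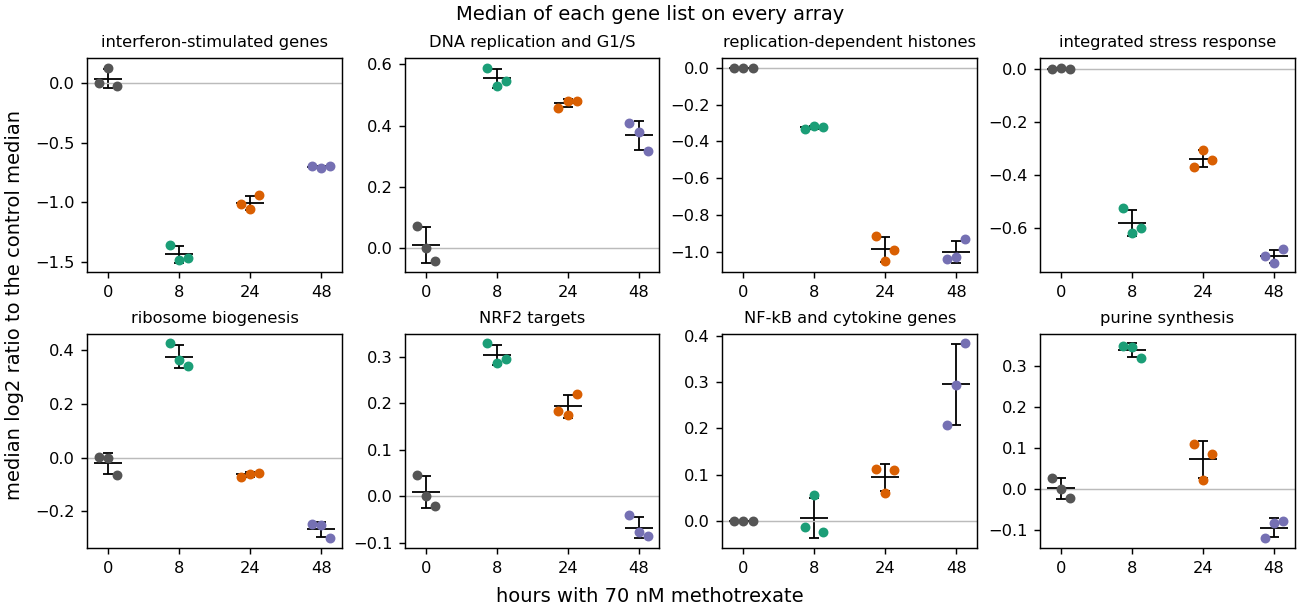
Median log2 ratio to the control median (vertical) of 8 gene lists on each array against hours with 70 nM methotrexate (horizontal); points are arrays, and bars show the mean and SD of 3. The interferon list lies at -1.49 to -1.35 at 8 h and at -0.71 to -0.70 at 48 h, and the ribosome biogenesis list goes from 0.34 to 0.42 at 8 h to -0.30 to -0.25 at 48 h.

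After 48 h, 40 of 45 replication-dependent histone genes were lower than control and 0 higher (41 and 0 adjusted over the list alone), with a median of -0.99. H2BC3 fell 4.66-fold (-2.22, SE 0.10, n = 3 per group) and the linker histone H1-5 3.94-fold (-1.98, SE 0.11). The list test gave adjusted p = 3.08e-37, and adjusted p = 0.00804 with an estimated correlation. Of 34 integrated stress response genes 29 fell and 1 rose (29 and 1 adjusted over the list alone), with a median of -0.72 (adjusted p = 2.19e-26, and adjusted p = 0.00993 with an estimated correlation). CHAC1 fell 4.76-fold (-2.25, SE 0.06), DDIT4 4.63-fold (-2.21, SE 0.08) and the cystine carrier SLC7A11 3.37-fold (-1.75, SE 0.09). Of 38 interferon-stimulated genes 33 fell and 0 rose (33 and 0 adjusted over the list alone), with a median of -0.74 (adjusted p = 9.93e-26, and adjusted p = 0.0261 with an estimated correlation). IFI44L was 4.20-fold lower (-2.07, SE 0.12). DEPTOR, which binds mTOR, fell 4.35-fold (-2.12, SE 0.08).

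NF-kB and cytokine genes rose in 19 of 29 cases at 48 h and fell in 2 (19 and 2 adjusted over the list alone), with a median of 0.25 (adjusted p = 1.31e-08, and adjusted p = 0.00993 with an estimated correlation). The median was 0.21, 0.29 and 0.38 on replicates 1, 2 and 3. The cytokine IL32 rose 3.96-fold (1.99, SE 0.07), IL18 2.65-fold (1.40, SE 0.11) and TNFAIP3, a feedback inhibitor of NF-kB, 2.56-fold (1.36, SE 0.07), while PTGS2, an inducible cyclooxygenase, fell 2.06-fold (-1.04, SE 0.08). The largest rises among all genes were LAPTM5, 5.13-fold (2.36, SE 0.13), CAV1, 4.92-fold (2.30, SE 0.10), complement C3, 4.35-fold (2.12, SE 0.08), EMP3, 4.04-fold (2.02, SE 0.07), IL32 and the adhesion molecule MCAM, 3.93-fold (1.97, SE 0.09). FN1, encoding fibronectin, rose by 1.0 (SE 0.10) and CD68 2.11-fold (1.08, SE 0.06), while their lists of fibroblast (2 of 22 higher, 1 lower; adjusted p = 0.379) and leukocyte and endothelial markers (1 of 18 higher, 0 lower; 0.399) were not past the threshold.

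Of 50 replication and G1/S genes 36 rose at 48 h and 2 fell (38 and 2 adjusted over the list alone), with a median of 0.40 (adjusted p = 6.75e-14, and adjusted p = 0.0939 with an estimated correlation). CDT1 rose 2.29-fold (SE 0.11 on the log2 scale) and the transcription factor E2F1 1.59-fold (0.67, SE 0.05). DNA damage repair genes rose in 15 of 34 cases and fell in 0 (15 and 1 adjusted over the list alone), with a median of 0.20 (adjusted p = 1.42e-05, and adjusted p = 0.497 with an estimated correlation). On the arrays of replicates 1, 2 and 3 that list's median was 0.30, 0.27 and 0.053. Ribosome biogenesis genes fell in 23 of 37 cases and rose in 0 (26 and 1 adjusted over the list alone), with a median of -0.27 (adjusted p = 1.18e-09, and adjusted p = 0.132 with an estimated correlation). DKC1, of the H/ACA small nucleolar particle, fell by 0.57 (SE 0.06) and RRP12 by 0.47 (SE 0.06). Ribosomal proteins fell in 8 of 31 cases and rose in 0 (8 and 0 adjusted over the list alone), with a median of -0.10 (adjusted p = 7.72e-05, and adjusted p = 0.0481 with an estimated correlation). Immediate early genes fell in 14 of 34 cases and rose in 7 (17 and 8 adjusted over the list alone), with a median of -0.16 (adjusted p = 0.000475, and adjusted p = 0.188 with an estimated correlation). On the 3 arrays the median was -0.15, -0.16 and -0.093. EGR1 fell 3.78-fold (-1.92, SE 0.07) and DUSP6, an ERK phosphatase, 2.38-fold (-1.25, SE 0.04).

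Cholesterol synthesis genes rose in 7 of 20 cases at 48 h and fell in 2 (8 and 2 adjusted over the list alone), among them SQLE (0.52, SE 0.05) and HMGCS1 (0.49, SE 0.07), with a median of 0.16 and adjusted p = 0.0184. The adjusted p = 0.414 with an estimated correlation, and the call was lost without control replicate 3 (0.0628) or 48 h replicate 1 (0.0504). Of 42 mitotic genes, 12 were higher and 6 lower (adjusted p = 0.268), which passed the threshold without 48 h replicate 3 (0.00981) or with array weights (0.0401). Folate genes (4 of 24 higher, 7 lower; 0.204), purine (2 of 17 higher, 5 lower; 0.106) and pyrimidine synthesis (7 of 20 higher, 5 lower; 0.715), methotrexate carriers (3 of 16 higher, 1 lower; 0.234), genes of resistant lines (3 of 11 higher, 2 lower; 0.399) and NRF2 targets (2 of 22 higher, 7 lower; 0.107) were not past it. TYMS rose 1.65-fold (0.72, SE 0.05) and GGH by 0.30 (SE 0.07), MTHFD2 fell by 0.55 (SE 0.06), and FOLR1 was 1.49-fold higher (0.57, SE 0.06). CDKN1A rose by 0.32 (SE 0.06), MUC2 rose by 0.21 (SE 0.05), and MYC fell by 0.63 (SE 0.06). SLC19A1 (0.04, SE 0.06, adjusted p = 0.750), FPGS (-0.12, SE 0.07, 0.272) and CCNE2 (-0.05, SE 0.06, 0.624) were not called, FPGS passing the threshold with array weights (0.00130). MKI67 (0.12, SE 0.11, 0.547) passed it without 48 h replicate 3 (0.0345) or with array weights (0.00320). The calls with array weights here rest mostly on 48 h replicate 2.

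Also not past the threshold at 48 h were p53 targets (7 of 32 higher, 8 lower; 0.420), the unfolded protein response and heat shock (7 of 22 higher, 3 lower; 0.412), apoptosis (5 of 30 higher, 3 lower; 0.480) and hypoxia and glycolysis (6 of 30 each way; 0.997). The same held for goblet (4 of 30 each way; 0.599), enterocyte (3 of 33 each way; 0.590), stem cell and Wnt (5 of 28 higher, 7 lower; 0.545) and enteroendocrine markers (0 of 18 called; 0.997), and for epithelial identity (3 of 12 higher, 1 lower; 0.496). CEACAM6 rose 2.08-fold (1.06, SE 0.08), and CREB3L1 was 2.67-fold lower (-1.42, SE 0.10). The median, mean and test differed in sign for the hypoxia and enteroendocrine lists. In the 18 lists not past the threshold, counts adjusted over the list alone differed from these by at most 2 higher and 3 lower members.

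In all, 2388 genes rose and 2261 fell at 48 h, 25.3% of those tested, with 75 and 88 changed at least 2-fold. The groups did not overlap for 35.7% of genes, against 10% by chance. With array weights, which rest mostly on replicate 2 at 48 h, the count was 7455. In the main fit the 48 h count was above the 8 h count (4649 against 4439). It was below the 8 h count without 48 h replicate 3 (4439 against 5161), without 48 h replicate 2 (4189 against 4265) and in fits of only the 2 groups (3849 against 4846).

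Between 8 h and 24 h, histone genes fell further, 42 of 45 with 0 higher (43 and 0 adjusted over the list alone; median -0.65; adjusted p = 1.01e-36, and adjusted p = 0.00645 with an estimated correlation). H3C12 fell 2.84-fold (-1.51, SE 0.07, n = 3 per group) and H1-5 2.82-fold (SE 0.11 on the log2 scale). Ribosome biogenesis genes fell in 30 of 37 cases and rose in 2 (32 and 2 adjusted over the list alone; median -0.47; adjusted p = 1.67e-21, and adjusted p = 0.0361 with an estimated correlation). Purine synthesis genes fell in 12 of 17 cases and rose in 2 (12 and 2 adjusted over the list alone; adjusted p = 3.63e-06, and adjusted p = 0.0478 with an estimated correlation). NF-kB and cytokine genes rose in 12 of 29 cases and fell in 2 (16 and 2 adjusted over the list alone; adjusted p = 1.16e-05, and adjusted p = 0.0361 with an estimated correlation). Interferon-stimulated genes rose in 19 of 38 cases and fell in 1 (22 and 1 adjusted over the list alone; median 0.32; adjusted p = 1.25e-10, and adjusted p = 0.152 with an estimated correlation). Integrated stress response genes rose in 18 of 34 cases and fell in 1 (20 and 3 adjusted over the list alone; adjusted p = 2.02e-10, and adjusted p = 0.0665 with an estimated correlation). The largest rises were TCP11L2 (1.53, SE 0.11), KRT23, an epithelial keratin (1.53, SE 0.10) and the phosphatase DUSP10 (1.51, SE 0.13), and AKR1B10 fell 2.55-fold (-1.35, SE 0.09). In all, 1836 genes rose and 1728 fell, and the groups did not overlap for 33.3% of genes, against 10% by chance.

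Of the 28 lists, 13 passed the threshold between 8 h and 24 h, 4 of them with an estimated correlation. Besides those above, mitotic genes fell in 14 of 42 cases and rose in 1 (18 and 1 adjusted over the list alone; adjusted p = 9.26e-06, and adjusted p = 0.340 with an estimated correlation). Replication and G1/S genes fell in 18 of 50 cases and rose in 2 (19 and 3 adjusted over the list alone; adjusted p = 2.44e-05, and adjusted p = 0.340 with an estimated correlation), and NRF2 targets fell in 7 of 22 and rose in 0 (12 and 0 adjusted over the list alone; adjusted p = 8.24e-05, and adjusted p = 0.0598 with an estimated correlation). Immediate early genes rose in 11 of 34 cases and fell in 1 (14 and 2 adjusted over the list alone; adjusted p = 0.00179, and adjusted p = 0.274 with an estimated correlation), and apoptosis genes rose in 7 of 30 and fell in 3 (9 and 5 adjusted over the list alone; adjusted p = 0.0176, and adjusted p = 0.340 with an estimated correlation). DNA damage repair genes fell in 8 of 34 cases and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.0213, and adjusted p = 0.662 with an estimated correlation), a call lost without 8 h replicate 1 (0.0955) or 24 h replicate 1 (0.0679). Pyrimidine and deoxynucleotide genes fell in 9 of 20 cases and rose in 3 (9 and 4 adjusted over the list alone; adjusted p = 0.0395, and adjusted p = 0.476 with an estimated correlation). That call was lost without 8 h replicate 1 (0.0708) or 24 h replicate 1 (0.0728), in a fit of only these 2 groups (0.0616), with the main residual axis as a covariate (0.0746) and over genes with a single probe set (0.0685).

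Between 24 h and 48 h, NRF2 targets fell in 13 of 22 cases and rose in 0 (14 and 0 adjusted over the list alone; median -0.24; adjusted p = 5.24e-14, and adjusted p = 0.00645 with an estimated correlation). AKR1B10 fell a further 2.21-fold (-1.14, SE 0.09, n = 3 per group). Integrated stress response genes fell in 25 of 34 cases and rose in 1 (25 and 1 adjusted over the list alone; median -0.32; adjusted p = 4.55e-21, and adjusted p = 0.0254 with an estimated correlation). NF-kB and cytokine genes rose in 12 of 29 cases and fell in 0 (13 and 0 adjusted over the list alone; adjusted p = 2.50e-10, and adjusted p = 0.00756 with an estimated correlation), with IL32 up 3.10-fold (1.63, SE 0.07). Interferon-stimulated genes rose in 23 of 38 cases and fell in 0 (29 and 1 adjusted over the list alone; median 0.36; adjusted p = 1.03e-18, and adjusted p = 0.0600 with an estimated correlation). Mitotic genes rose in 15 of 42 cases and fell in 0 (24 and 1 adjusted over the list alone; adjusted p = 1.80e-12, and adjusted p = 0.141 with an estimated correlation). Cholesterol synthesis genes rose in 6 of 20 cases and fell in 0 (13 and 0 adjusted over the list alone; adjusted p = 4.18e-07, and adjusted p = 0.0665 with an estimated correlation). Complement C3 rose 2.82-fold (SE 0.08 on the log2 scale) and the uroplakin UPK2 2.48-fold (1.31, SE 0.11), while ANXA10 fell 2.65-fold (-1.41, SE 0.08) and the calcium-binding protein CALB2 2.20-fold (-1.14, SE 0.06). In all, 966 genes rose and 894 fell, and the groups did not overlap for 24.0% of genes, against 10% by chance. With at least a 1.5-fold change 103 of 136 were higher (75.7%), with treat against a 1.2-fold change 84 of 128 (65.6%), and with array weights 2769 of 5901 (46.9%). The total of 1860 fell to 1104 without 24 h replicate 1, to 1103 without 24 h replicate 3, and to 1022 in a fit of only these 2 groups, and it was 5901 with array weights and 3768 with the main residual axis as a covariate.

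Between 24 h and 48 h 11 of the 28 lists passed the threshold, 4 of them with an estimated correlation. The remaining ones were ribosome biogenesis, with 13 of 37 lower and 0 higher (22 and 0 adjusted over the list alone; median -0.22; adjusted p = 3.26e-11, and adjusted p = 0.0968 with an estimated correlation), and replication and G1/S, with 12 of 50 lower and 0 higher (13 and 0 adjusted over the list alone; adjusted p = 7.49e-07, and adjusted p = 0.281 with an estimated correlation). Purine synthesis genes fell in 6 of 17 cases and rose in 0 (6 and 0 adjusted over the list alone; adjusted p = 6.97e-06, and adjusted p = 0.0489 with an estimated correlation). Ribosomal proteins had 1 of 31 lower and 0 higher (1 and 0 adjusted over the list alone; median -0.067; adjusted p = 0.0395, and adjusted p = 0.281 with an estimated correlation). That call was lost without 24 h replicate 1 (0.0794), 24 h replicate 3 (0.0626) or 48 h replicate 3 (0.134), with array weights (0.0651), in a fit of only these 2 groups (0.0616), with the main residual axis as a covariate (0.0747) and over genes with a single probe set (0.0676). Pyrimidine and deoxynucleotide genes had 4 of 20 lower and 2 higher (8 and 2 adjusted over the list alone; adjusted p = 0.0408, and adjusted p = 0.476 with an estimated correlation). This was lost without control replicate 2 (0.0504), 8 h replicate 1 (0.0570), 24 h replicate 2 (0.0952) or 3 (0.0607) or 48 h replicate 3 (0.134), with array weights (0.191), in a fit of only these 2 groups (0.0616) and with the main residual axis as a covariate (0.0938).

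**Figure D4:**
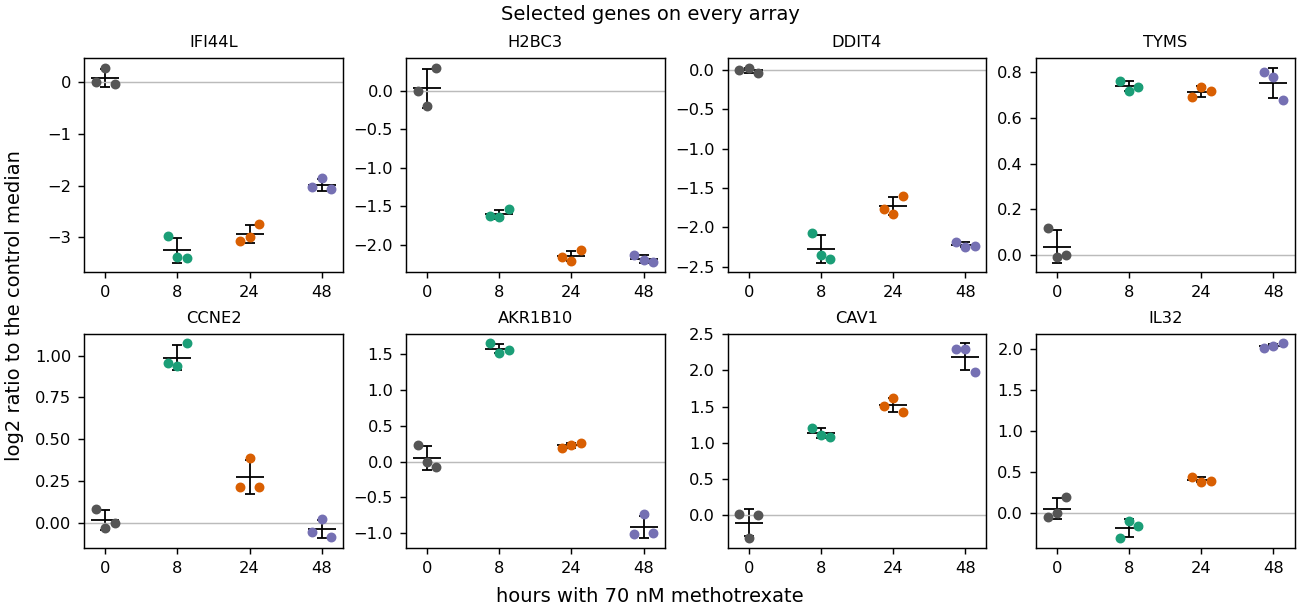
Log2 ratio to the control median (vertical) of 8 genes on each array against hours with 70 nM methotrexate (horizontal); points are arrays, and bars show the mean and SD of 3. TYMS is higher by 0.70, 0.68 and 0.72 at 8, 24 and 48 h, while AKR1B10 is higher by 1.53 at 8 h and lower than control at 48 h (-0.97).

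Across the 3 times, 7199 genes were called against control at 1 time at least, 576 higher and 677 lower at all 3 times. At 8 h and 24 h, 793 genes were higher and 903 lower at both, and 160 were called in opposite directions. Independent lists of these sizes would share 193 higher and 177 lower genes with 371 opposite, and simulated unchanged groups shared 0. At 8 h and 48 h, 708 were higher and 874 lower at both, and 657 opposite, against 289, 272 and 561 for independent lists and 0.030 and 0.040 in the simulations. At 24 h and 48 h, 1186 were higher and 1063 lower at both, and 23 opposite, against 208, 181 and 388 for independent lists and 0 in the simulations. Across genes, which are not independent replicates, fold changes correlated at 0.605, 0.365 and 0.794 for these pairs of times, against 0.429, 0.481 and 0.422 in the simulations, so that the value for 8 h and 48 h lay below the simulated one. The covariances were 0.0318, 0.0227 and 0.0435, against 0.00264, 0.00321 and 0.00291, with differences of 0.0292, 0.0195 and 0.0405. The simulated groups had no effects and so few calls to share, and their counts near 0 do not measure what the shared controls add. The 3 control arrays are too few to split, so part of the excess of shared calls over independent lists may come from the shared controls.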

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

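Removal of the main residual axis and the comparison with histone genes outside the clusters were set before their results were seen. The tests of 48 h against 8 h, the replication genes, the untreated arrays, the splits and the tests of other probe sets were chosen after the results were seen. Centring and leaving out each array were settings fixed beforehand, and only their use as tests of these patterns was chosen afterwards.

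Some named genes were called against control in opposite directions at different times. They were picked for this, so the p-values of the differences, from limma, were bound to be small and add no support of their own. AKR1B10 was higher than control at 8 h (1.53) and lower at 48 h (-0.97), a difference of -2.49 (adjusted p = 1.24e-09). CALB2 was higher at 8 h (0.33) and lower at 24 h (-0.18, difference -0.51, adjusted p = 4.01e-05) and at 48 h (-1.32, difference -1.64, adjusted p = 1.24e-09). CDKN1A went from -0.45 at 8 h to 0.32 at 48 h (difference 0.77, adjusted p = 1.30e-06). DUSP10 went from -0.82 at 8 h to 0.69 at 24 h (difference 1.51, adjusted p = 6.33e-06) and 0.84 at 48 h (difference 1.66, adjusted p = 8.64e-07). IL32 went from -0.24 at 8 h to 0.35 at 24 h (difference 0.59, adjusted p = 5.65e-05) and 1.99 at 48 h (difference 2.23, adjusted p = 7.42e-10). KRT23 went from -0.61 at 8 h to 0.92 at 24 h (difference 1.53, adjusted p = 9.14e-07) and 0.83 at 48 h (adjusted p = 2.27e-07), the latter difference being 1.44. Among the 9559 probe sets with several genes or none named, which the comparisons of genes did not use, 487 were called against control at 8 h, 335 at 24 h and 666 at 48 h.

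Interferon-stimulated genes were lower at 8 h than in control, with a list median of -1.45 (bootstrap SE 0.09). After the part of the fold changes that follows the main residual axis with a single slope over all genes was removed, the median was -1.44. Across genes the axis loadings correlated with the 8 h fold changes at only 0.138, so the removal could move a list little. It therefore does not decide whether the axis contributes to the fall. The axis comes from differences within groups, so its removal does not test a shift of another kind shared by all arrays of a group. The highest median over the fits without 1 control array was -1.40, so a single control array with a high level does not account for the fall. Time in culture or a change of medium cannot be told apart from methotrexate, since 0 untreated arrays at 8 h were analysed. An effect of methotrexate on these genes may therefore underlie the fall, as may a signal present in the cells at 0 h that had declined by 8 h. The list median lay at -1.49 to -1.35 on the 8 h arrays, -1.05 to -0.94 at 24 h and -0.71 to -0.70 at 48 h. A signal that only declined with time would not rise again after 8 h. These values thus argue against such a decline as the whole account.

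Replication-dependent histone genes were lower at 24 h than in control, with a list median of -0.96 (bootstrap SE 0.06). The median was -0.99 with the main residual axis removed. The axis loadings correlated with the 24 h fold changes at only 0.221, so this removal could move a list little and does not decide. The 7 measured histone genes outside the clusters had a median of -0.085 (bootstrap SE 0.12), with 3 of them called lower and H1-10 lowest at -0.67, so a fall of histone probe sets in general does not account for the size of the shift. Genes of DNA replication and G1/S were higher, with a median of 0.48 (bootstrap SE 0.05), which argues against withdrawal before G1/S but not against a stop later in the cycle, since 18 of 42 mitotic genes were lower and 4 higher (median -0.12, adjusted p = 0.000194, and adjusted p = 0.452 with an estimated correlation). Time in culture or a change of medium cannot be told apart from methotrexate, with 0 untreated arrays at 24 h. A hypothesis that stays open is that cells with active G1/S genes made less DNA, since transcripts of these histones may depend on ongoing DNA synthesis, which was not measured.

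Ribosome biogenesis genes, picked in the same way, were higher than control at 8 h (median 0.38, bootstrap SE 0.06, adjusted p = 0.0508 with an estimated correlation) and lower at 48 h (median -0.27, bootstrap SE 0.04, adjusted p = 0.132 with an estimated correlation), a difference of -0.65 (adjusted p = 1.25e-21 with the preset correlation, and adjusted p = 0.0213 with an estimated correlation). With the main residual axis removed by a single slope over all genes, the values were 0.41 and -0.26. The axis loadings correlated with the fold changes at only 0.138 at 8 h and 0.180 at 48 h. Such a removal could move a list little, so it does not decide whether the axis contributes to the change of sign. Normalization between arrays stays open, since centring, which left the 48 h value at -0.27, moves all genes of an array alike and the array medians were only -0.014 to 0.026. Time in culture or a change of medium cannot be told apart from methotrexate, with 0 untreated arrays at 48 h. A fall in growth with time in culture may therefore contribute, as may the drug or the normalization.

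The real grouping was 1 of 10 splits of the arrays of each pair of groups, too few for a share under 0.05. At 8, 24 and 48 h against control and at 24 h against 8 h it called 4439, 3070, 4649 and 3564 genes, and the highest other split called 0 in each. At 48 h against 24 h it called 1860 genes and the highest other split 893. That split set 48 h replicates 1 and 2 with 24 h replicate 2, the arrays with low scores on the main residual axis (-0.388, -0.220 and -0.363). For differences among the 4 groups, the real grouping called 7122 genes, and the highest of the other splits among 100 called 1511. Only 1 of 100 reached the real count, the smallest share these splits can give. Chance is thus unlikely for this count, but the splits cannot separate treatment from anything else shared by the arrays of a group.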

How the results depend on the processing

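The main residual axis as a covariate and only genes with a single probe set were chosen after seeing the data; the other settings were fixed beforehand. No gene or list that was named changed direction while called. Centring each array, the robust prior, every probe set on its own and only genes with a single probe set kept each count of genes within 1.5 times its value. Where a count moved further, the cause was not tested unless the setting itself is a stricter threshold.

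Counts are given in the order 8, 24 and 48 h against control, 24 h against 8 h, and 48 h against 24 h, where they moved by over 1.5 times. At an adjusted p under 0.01 they were 2920, 1770, 2252 and 819, without 48 h, which stayed closer. With at least a 1.5-fold change they were 598, 442, 688, 435 and 136, and 1147 for differences among the 4 groups. With treat against a 1.2-fold change they were 831, 492, 934, 527 and 128. Array weights gave 6079 at 24 h, 7455 at 48 h, 5901 at 48 h against 24 h and 11190 among the 4 groups. At 48 h those weights rest mostly on replicate 2. The residual axis as a covariate gave 5234 at 24 h and 3768 at 48 h against 24 h. A fit of only the 2 groups gave 1022 at 48 h against 24 h.

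In that order, 50.1%, 52.0%, 51.4%, 51.5% and 51.9% of the called genes were higher. Over all settings, those without an array included, the shares were 36.6% to 53.5%, 41.2% to 58.2%, 47.3% to 55.6%, 47.3% to 60.3% and 46.9% to 75.7%. With at least a 1.5-fold change they were 36.6%, 41.2%, 50.7%, 57.2% and 75.7%.

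Genes called in the same direction at 2 times numbered 1696 for 8 and 24 h, 1582 for 8 and 48 h and 2249 for 24 and 48 h. In that order they were 3282, 2734 and 3957 with array weights, 940, 930 and 1322 at an adjusted p under 0.01, 216, 187 and 307 with at least a 1.5-fold change, 270, 260 and 363 with treat, and 2891, 2558 and 3749 with the residual axis. Of the 84 list tests, 33 passed with the preset correlation, 17 with an estimated correlation and 54 with fry, which does not compare a list with other genes.

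A fit of only the 2 groups ended the calls of RPL34 at 8 h, ABCC5, SC5D and TAGLN at 24 h, and SAMHD1, BAD, RPL22 and TAGLN at 48 h (adjusted p 0.0507 to 0.0871). It also ended those of goblet markers at 8 h (0.0852) and, at 0.0616 each, of pyrimidine synthesis in both consecutive comparisons and ribosomal proteins at 48 h against 24 h. The residual axis ended the last 3 too (0.0746, 0.0938 and 0.0747), and those of resistant-line genes (0.0557) and goblet markers (0.0837) at 8 h and NF-kB genes at 24 h (0.0557). Ribosome biogenesis genes (0.0266), CCK (0.0144) and GGH (0.0131) at 24 h passed with the axis, as did GGH at 8 h (0.00467), which also passed with the 2-group fit (0.0261). List calls against control numbered 32 with the 2-group fits and 31 with the axis.

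Leaving out each array in turn gave 3403 to 5161 genes at 8 h, 2102 to 3938 at 24 h, 3704 to 4749 at 48 h, 2726 to 4294 at 24 h against 8 h, 1103 to 2149 at 48 h against 24 h and 6261 to 7720 among the 4 groups. The shared calls were 1151 to 2184, 1138 to 1643 and 1602 to 2474, and 31 to 33 lists passed.

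With the replicate block the counts were 4718, 3390, 5006, 3823 and 2119, 7548 among the 4 groups, 1892, 1746 and 2480 for shared calls, and 32 lists. It ended the calls of RPL34 at 8 h (0.0590), CLDN3 (0.0551) and TAGLN (0.0584) at 24 h, goblet markers at 8 h (0.0529), NF-kB genes at 24 h (0.0507) and pyrimidine synthesis in both consecutive comparisons (0.0507 and 0.0688). GGH (0.0263) and apoptosis genes (0.0478) at 8 h and CCK at 24 h (0.0386) passed with it, and no named gene or list changed its call at 48 h against control. Over all groups the numbers did not show a pairing: 11 of 18 same-numbered pairs of arrays had a correlation of deviations over 0.1 (range -0.452 to 0.472), and 6 of 12 arrays correlated best with their own number. For control and 48 h alone, all 3 pairs were over 0.1 (0.349, 0.117 and 0.458). Not run were the brightest probe set per gene, the filter on dim probe sets and the trended prior, which need the lost level, a second quantile normalization, since centring makes the control arrays narrower, and a slide block, since no slide or scan date was used here. With the level lost, what signal over background limits is unknown.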

Other observations

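The 27 gene families tested here were formed by symbol and chosen after the data were seen. Of 81 camera tests, 24 passed with the preset correlation and 0 with an estimated correlation. Only some are described in detail. H/ACA box small nucleolar RNAs were lower at 24 h in 17 of 61 cases and higher in 0. Their adjusted p = 2.28e-05, and 0.328 with an estimated correlation. Tubulins passed upward at 8, 24 and 48 h, and integrins and laminins at 24 and 48 h. Zinc fingers passed downward at 8 and 24 h, translation initiation factors at 48 h and amino acid carriers at 24 h. Genes of mitochondrial ribosomal proteins rose in 34 of 74 cases at 8 h and fell in 0 (median 0.16, adjusted p = 3.91e-08, and adjusted p = 0.0855 with an estimated correlation). At 24 h 7 rose and 5 fell (adjusted p = 0.949), and at 48 h, 2 rose and 23 fell (median -0.081, adjusted p = 0.000368, and adjusted p = 0.217 with an estimated correlation). MRPS25 rose by 0.55 at 8 h (SE 0.06), and MRPL3 rose by 0.28 at 8 h and fell by 0.55 at 48 h (SE 0.05, n = 3 per group). Complex I subunits and assembly factors fell in 17 of 42 cases at 48 h and rose in 1 (median -0.17, adjusted p = 0.000227, and adjusted p = 0.120 with an estimated correlation). At 24 h 0 rose and 9 fell (adjusted p = 0.00135, and adjusted p = 0.204 with an estimated correlation), while at 8 h 9 were higher and 0 lower (median 0.074, adjusted p = 0.123). Of 115 C/D box small nucleolar RNAs, which guide methylation of ribosomal RNA, 27 rose at 8 h and 0 fell (adjusted p = 0.00122, and adjusted p = 0.456 with an estimated correlation). SNORD30 rose by 1.14 at 8 h (SE 0.07). At 24 h, 0 rose and 19 fell (adjusted p = 0.000227, and adjusted p = 0.405 with an estimated correlation), and at 48 h 6 were higher and 6 lower (adjusted p = 0.852). The median loading on the main residual axis was -0.0632 for these RNAs, -0.0258 for mitochondrial ribosomal proteins and -0.0224 for complex I.

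Keratin genes, which encode intermediate filaments of epithelia, rose in 10 of 46 cases at 24 h and fell in 0 (adjusted p = 0.000309, and adjusted p = 0.456 with an estimated correlation). At 48 h, 9 rose and 0 fell (adjusted p = 0.0286, and adjusted p = 0.757 with an estimated correlation), and at 8 h 3 were higher and 1 lower (adjusted p = 0.182). KRT13 was higher than control by 1.36 at 24 h and 1.18 at 48 h (SE 0.06), and KRT80 by 1.33 and 1.15 (SE 0.08). Kallikreins, a cluster of secreted proteases, rose in 6 of 15 cases and fell in 0 at 24 h (adjusted p = 0.000329) and at 48 h (adjusted p = 0.000717), with adjusted p = 0.328 with an estimated correlation at both times. At 8 h 4 rose and 0 fell (adjusted p = 0.0258, and adjusted p = 0.456 with an estimated correlation). KLK5 was higher by 0.86 at 24 h and 1.66 at 48 h (SE 0.08). Both families load on the main residual axis, on which 48 h replicate 3 scores highest, with a median loading of 0.108 for keratins and 0.169, the highest of the families, for kallikreins. Across genes, the loadings correlated with the fold changes at 0.138, 0.221 and 0.180 at 8, 24 and 48 h. Genes with proteasome symbols, which take in assembly factors and PSMC3IP, a cofactor of recombination, rose in 21 of 47 cases at 8 h and fell in 4 (median 0.15, adjusted p = 0.000368, and adjusted p = 0.328 with an estimated correlation). At 24 h 4 were higher and 2 lower (adjusted p = 0.852), and at 48 h 7 were higher and 11 lower (median -0.063, adjusted p = 0.143). Their median loading was -0.0210.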
